A study of Arabidopsis thaliana with 12 samples.

How the data were processed

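RNA from whole seedlings of 4 genotypes was labelled as biotinylated cRNA and hybridised to Affymetrix arrays, with 3 arrays per genotype. Per the labels, seedlings were kept in the cold for 48 h, exposed to white light of 100 µmol for 6 h and grown at 22 °C in darkness for 4 days on medium without sugar. The deposited values are read as log2 intensities, 1 per locus and array. The labels do not state the log base, which was taken from the range of the values, nor the array type, the background correction, the probe summary or the software. The sorted values of all 12 arrays were identical, so the authors had given the arrays a common distribution, and the values were used as deposited. The table held 27827 loci with no control entries, no missing values and no detection calls. Group means below the mean of RLP44 over all arrays are described as near background. Locus identifiers were matched to a gene table for symbols and order on the chromosomes, which held 27241 of them and left 586 unmatched. The number of arrays limits the precision.

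Differences between genotypes were tested with limma (version 3.58.1, R 4.3.3) by lmFit on the group means of all 12 arrays and eBayes, with 8 residual and 4.06 prior degrees of freedom. Values of p were two-sided and adjusted by Benjamini-Hochberg over all loci, and a locus was called at an adjusted p under 0.05. The 6 comparisons were PMEIox, cnu1 and cnu2 against Col-0, cnu1 and cnu2 against PMEIox, and cnu1 against cnu2. All log2 differences are the first genotype minus the second. The model, the lists, the rule for named genes and the alternatives not marked otherwise were chosen before the data were examined.

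Named genes are, in each comparison, PMEI5, BRI1 and RLP44, the 10 largest rises and the 10 largest falls among called loci whose 3 against 3 values do not overlap, and up to 4 members of each list with the smallest adjusted p. Genes named beyond this rule are said to be so. The 27 lists cover brassinosteroid synthesis, catabolism, signalling and induced genes, auxin, ethylene, gibberellin and jasmonate genes, defence, wall receptors, pectin methylesterases and their inhibitors, pectin depolymerases and synthesis, expansins, XTH genes, primary and secondary walls, flavonoids, cuticle, root hairs, roots, seed storage, photosynthesis and light, heat shock, cell division and reference genes. They held 413 members, all measured, from 404 loci. TCH4, EXPA8, EXPA1, KCS1, IAA19 and ACS5 are in the brassinosteroid-induced list and in another, EXPA7 and EXPA18 are expansins and root hair markers, and XTH14 is an XTH gene and a root hair marker. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison, with a correlation estimated from the data, and with fry, which does not compare a list with other genes. Members were also counted when adjusted over the list alone.

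Loci called in PMEIox against Col-0 and called with the opposite sign in a suppressor against PMEIox were counted as moved back. Because both comparisons use the PMEIox arrays, correlations and covariances across genes were set beside 100 simulated sets of unchanged groups sharing arrays. The simulated values were drawn independently for each locus and array, so the simulated ranges leave out deviations that arrays have in common. The score of an array is its position on the line from the Col-0 mean to the PMEIox mean over the changed loci other than PMEI5, in percent, and was compared between the suppressors by an exact permutation test. The procedure was tested on simulated data with 50 changed loci at each size, of which 24% were called at a log2 change of 0.5, 84% at 1 and 100% at 2 and at 3, with 10 false calls.

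The alternatives were quantile normalization, median centring, leaving out the lowest 40% of loci (16696 remained), eBayes with trend and robust settings (statmod 1.5.0), array weights, a fit of the compared genotypes alone, a minimum fold of 2, the replicate letter as a block, and leaving out each array in turn. Centring on 10 reference genes, the doubt about array A of Col-0, and the inhibitor list without PMEI5 were added after seeing the data. Alternative gene summaries and the handling of probe sets with several genes could not be run, since the table holds a single entry per locus. Sample entries other than the values were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.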

Results

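Transcript levels were measured on 12 arrays with RNA from whole Arabidopsis thaliana seedlings grown in darkness for 4 days. The genotypes were Col-0, which is the wild type, PMEIox, which overexpresses an inhibitor of pectin methylesterases, PMEI5 (AT2G31430), and cnu1 and cnu2, which are suppressors of the PMEIox phenotype in the PMEIox background. Pectin methylesterases remove methyl groups from pectin in the cell wall. The cnu1 line is known to carry a mutation in BRI1 (AT4G39400), the brassinosteroid receptor, and the cnu2 line a mutation in RLP44 (AT3G49750), a receptor-like protein. Each genotype had 3 biological replicates, named A, B and C, which the design text places in successive weeks. The table gave 1 log2 value for each of 27827 loci on each array, from 0.785 to 13.9 with a median of 5.47. Pearson correlations between arrays across genes, which are not independent replicates, ran from 0.983 to 0.994. The number of arrays limits the precision, and the median standard error of a log2 difference between genotypes was 0.137.

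The comparison of PMEIox with Col-0 asked which transcripts differ in seedlings that carry the transgene. Seed storage transcripts were higher in PMEIox, with a list median of 2.22 on the log2 scale, and transcripts of secondary wall enzymes were lower (median -0.73). With the preset correlation alone, expansins, XTH genes and pectin depolymerases were called higher and brassinosteroid synthesis genes lower (median -0.36), but these calls ended with an estimated correlation (adjusted p from 0.0817 to 0.207). Of their members 4 of 25, 7 of 33 and 7 of 18 rose and 4 of 10 fell. PMEI5 rose by 6.75 ± 0.67 (SE, adjusted p = 0.000109), from 5.91 ± 1.99 (SD, n = 3) in Col-0 to 12.66 ± 0.03 (SD, n = 3) in PMEIox. Within Col-0, array A had a PMEI5 value of 8.19, array B 5.05 and array C 4.49, and without Col-0 A PMEI5 differed by 7.89. BRI1 differed by -0.13 ± 0.09 (SE, adjusted p = 0.501) and RLP44 by -0.08 ± 0.20 (SE, adjusted p = 0.883), and the mean of RLP44 lay above that of 14.8% of the loci on these arrays.

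In PMEIox, 1460 loci passed the test against Col-0, 775 higher and 685 lower, of which 185 and 134 differed at least 2-fold. Besides PMEI5, the largest rises included EARLI1 (AT4G12480), a lipid transfer protein gene, at 4.27 ± 0.37 (SE, adjusted p = 5.03e-05), and EB1a (AT3G47690), which encodes a microtubule end-binding protein, at 3.70 ± 0.16 (SE, adjusted p = 4.15e-07). EB1a stood at 6.22 ± 0.13 (SD, n = 3) in Col-0 and 9.92 ± 0.36 (SD, n = 3) in PMEIox. Large rises were also those of the storage protein genes CRA1 (AT5G44120), CRU3 (AT4G28520), SESA3 (AT4G27160) and SESA1 (AT4G27140), of the defensin-like gene LCR67 (AT1G75830), of M17 (AT2G41260), a late embryo gene, and of AT5G39150, from at least 2.96 for AT5G39150 to 3.77 for CRA1. In Col-0 AT5G39150 stood at 2.12, near background, so its difference is a lower bound. Among the falls, CYP705A5 (AT5G47990), a cytochrome P450 gene of thalianol metabolism, fell by 3.21 ± 0.24 (SE, adjusted p = 1.59e-05), and AT4G11320 fell by 2.89 ± 0.13 (SE, adjusted p = 4.15e-07). ENODL1 (AT5G53870), AT4G11190, AT5G57785, AT2G16005, AT4G17470, the laccase gene LAC2 (AT2G29130), CYP710A2 (AT2G34490), which encodes a sterol desaturase, and MLP34 (AT1G70850) also fell, with log2 differences from -2.70 for ENODL1 to -2.18 for MLP34. The 3 values of PMEIox and the 3 of Col-0 did not overlap at 22.9% of all loci, where chance gives 10%. The replicate letter as a block gave 1596 loci, the fit of these genotypes alone 868, a minimum fold of 2 319, and leaving out PMEIox A, PMEIox B or Col-0 B 882, 932 and 895. With the arrays centred on 10 reference genes 541 were higher and 904 lower, which puts the share of higher loci at 37.4% in place of 53.1%.

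Seed storage markers formed the list with the largest median difference between PMEIox and Col-0 among the 27. Of 13 markers, 12 rose and 0 fell (13 and 0 adjusted over the list alone, median 2.22, camera adjusted p = 1.45e-24, and adjusted p = 0.0135 with an estimated correlation). SESA3, a storage albumin gene, rose by 3.49 ± 0.19 (SE, adjusted p = 2.64e-06), from 6.39 ± 0.22 to 9.88 ± 0.17 (SD, n = 3 each). OLEO1 (AT4G25140), which encodes an oil body protein, rose by 1.95 ± 0.15 (SE, adjusted p = 2.12e-05).

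Brassinosteroid genes moved in both directions in PMEIox. Of 10 brassinosteroid synthesis genes, 0 rose and 4 fell (1 and 5 adjusted over the list alone, median -0.36, camera adjusted p = 0.000331, and adjusted p = 0.0817 with an estimated correlation). DWF4 (AT3G50660), which encodes an early, rate-limiting hydroxylase, fell by 1.41 ± 0.14 (SE, adjusted p = 0.000101). CPD (AT5G05690) fell by 1.28, BR6OX2 (AT3G30180) by 1.05 and CYP90D1 (AT3G13730) by 0.70. Of 7 catabolism genes, 2 rose and 0 fell (2 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.0482, and adjusted p = 0.207 with an estimated correlation). Among them were BAS1 (AT2G26710), which inactivates brassinosteroids, at 1.19 and BEN1 (AT2G45400) at 0.67. The catabolism call ended without Col-0 A (adjusted p = 0.109), Col-0 C (adjusted p = 0.0557) or PMEIox C (adjusted p = 0.188), without the lowest 40% of loci (adjusted p = 0.0613) and with the replicate block (adjusted p = 0.0741). Of 16 genes known to be induced by brassinosteroids, 7 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.40, camera adjusted p = 0.00159, and adjusted p = 0.207 with an estimated correlation). BEE1 (AT1G18400) rose by 1.01 and TCH4 (AT5G57560), also an XTH gene, by 0.96, while PRE1 (AT5G39860) fell by 1.70 and EXL2 (AT5G64260) by 0.61. Of 16 brassinosteroid signalling genes 0 passed limma's test, with 4 at an unadjusted p under 0.05, and camera pointed down (adjusted p = 0.994) while the median was 0.03. That median lay below 0 with centring on the reference genes, which left 5 rises and 2 falls among the induced genes and 2 rises and 1 fall among the catabolism genes.

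Other hormone lists were also called between PMEIox and Col-0. With centring on the reference genes 3 auxin response genes rose and 2 fell, and 2 gibberellin genes rose and 1 fell. Of 33 auxin response genes, 5 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 4.25e-05, and adjusted p = 0.207 with an estimated correlation). SAUR9 (AT4G36110) rose by 1.75, while IAA29 (AT4G32280) fell by 1.07 and LBD29 (AT3G58190) by 1.14. Of 16 ethylene genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.0122, and adjusted p = 0.16 with an estimated correlation), among them the ethylene synthesis genes ACS8 (AT4G37770) at 1.41 and ACS5 (AT5G65800) at 0.93, the latter also in the brassinosteroid-induced list. The ethylene call ended without Col-0 B (adjusted p = 0.0528). Of 8 gibberellin genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.0199, and adjusted p = 0.0885 with an estimated correlation). GA20OX2 (AT5G51810), a gibberellin synthesis gene, rose by 1.64 and GASA6 (AT1G74670) fell by 1.57. Of 17 jasmonate genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone, median -0.14, camera adjusted p = 0.0336, and adjusted p = 0.207 with an estimated correlation). JR1 (AT3G16470), a jasmonate-responsive lectin gene, fell by 2.01. The calls of the other members AOS, VSP1 and JAZ10 ended in 5, 4 and 3 of the omissions of an array. Their adjusted p then ran from 0.0752 to 0.113, from 0.0622 to 0.0788 and from 0.0571 to 0.0622. The jasmonate call ended without Col-0 B (adjusted p = 0.152) or PMEIox A (adjusted p = 0.0576) and without the lowest 40% of loci (adjusted p = 0.0745).

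Wall enzyme lists called between PMEIox and Col-0 had medians above 0. With centring on the reference genes 3 pectin methylesterases rose and 2 fell (median 0.05), 4 expansins rose and 1 fell, and 2 pectin synthesis genes, 6 XTH genes and 0 primary wall cellulose genes rose. Of 31 pectin methylesterases, 5 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.00497, and adjusted p = 0.152 with an estimated correlation). Among them were AT2G26440 at 1.83 and AT5G04970 at 1.58. Of 12 pectin methylesterase inhibitors other than the transgene PMEI5, which was left out after seeing the data, 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.0336, and adjusted p = 0.166 with an estimated correlation), namely AT4G25260 at 0.84 and AT1G62770 at 0.55. The call of these inhibitors ended without Col-0 A (adjusted p = 0.0696), Col-0 C (adjusted p = 0.081) or PMEIox B (adjusted p = 0.0844). Of 18 pectin depolymerases, 7 rose and 0 fell (10 and 2 adjusted over the list alone, median 0.36, camera adjusted p = 0.000541, and adjusted p = 0.0817 with an estimated correlation), among them the pectate lyase-like gene AT5G63180 at 1.46 and the polygalacturonase gene PGAZAT (AT2G41850) at 0.79. Of 9 pectin synthesis genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 5.75e-05, and adjusted p = 0.0885 with an estimated correlation), with GALS1 (AT2G33570) at 0.69. Of 25 expansins, 4 rose and 0 fell (10 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 0.0142, and adjusted p = 0.207 with an estimated correlation). Among them were EXPA12 (AT3G15370) at 0.76 and EXPA18 (AT1G62980) at 1.07. The expansin call ended without the lowest 40% of loci (adjusted p = 0.317). Of 33 xyloglucan-modifying XTH genes, 7 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 1.07e-06, and adjusted p = 0.0817 with an estimated correlation). One of them was XTH33 (AT1G10550) at 1.18. Of 9 genes of primary wall cellulose, 1 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0142, and adjusted p = 0.207 with an estimated correlation). COB (AT5G60920) was the called gene at 0.49. The COB call ended without Col-0 A, Col-0 B, Col-0 C, PMEIox A or PMEIox B (adjusted p from 0.0891 to 0.158), with the replicate block (adjusted p = 0.0601) and with centring on the reference genes (adjusted p = 0.0845).

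Secondary wall and lignin genes went the other way in PMEIox. Of 10 genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone, median -0.73, camera adjusted p = 2.15e-09, and adjusted p = 0.0384 with an estimated correlation). IRX12 (AT2G38080), a lignin laccase gene, fell by 1.21 ± 0.16 (SE, adjusted p = 0.000937), from 9.27 ± 0.26 to 8.06 ± 0.13 (SD, n = 3 each). XCP1 (AT4G35350), a xylem protease gene, fell by 1.14 and the cellulose synthase gene IRX3 (AT5G17420) by 0.79. Of 8 flavonoid genes, 0 rose and 3 fell (1 and 4 adjusted over the list alone, median -0.40, camera adjusted p = 0.0063, and adjusted p = 0.0817 with an estimated correlation), among them TT4 (AT5G13930), which encodes chalcone synthase, at -0.81 and F3H (AT3G51240) at -0.87.

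Markers of other organs and of sample state were measured for PMEIox and Col-0. Of 15 root hair markers, 5 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.76, camera adjusted p = 1.07e-06, and adjusted p = 0.0817 with an estimated correlation). Among them were EXT10 (AT5G06640) at 2.55 and RHS19 (AT5G67400) at 2.29, and EXPA18 is in this list and among the expansins. Of 9 root markers, 11 wall receptors, 8 cell division genes and 10 reference genes, 0 passed limma's test, with 1, 3, 1 and 2 at an unadjusted p under 0.05. Camera gave adjusted p = 0.431, 0.205, 0.466 and 0.325 for these lists. Of 24 defence genes 3 rose, PGIP2 (AT5G06870) at 0.54 among them, and of 15 cuticle genes 2 rose and 1 fell (camera adjusted p = 0.977 and 0.325 for these lists). The call of the defence gene PR5 ended in 6 of the omissions of an array (adjusted p from 0.0583 to 0.155). Those of the cuticle genes LP1, LTP2 and LACS1 ended in 6, 6 and 5 (adjusted p up to 0.139, 0.158 and 0.151). With centring on the reference genes 0 cuticle genes rose and 1 fell, with a median of -0.04 in place of 0.03, and 2 defence genes rose and 1 fell. Of 22 photosynthesis and light markers 1 fell, ELIP2 (AT4G14690) at -1.08, and camera gave adjusted p = 0.107 for the list. Of 7 heat shock genes 1 rose, HSP17.4 (AT3G46230) at 0.83, and camera gave adjusted p = 0.991 for the list. The defence median was -0.05 and the heat shock median -0.15, while camera pointed up for both and the mean was above 0 for heat shock.

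**Figure D1:**
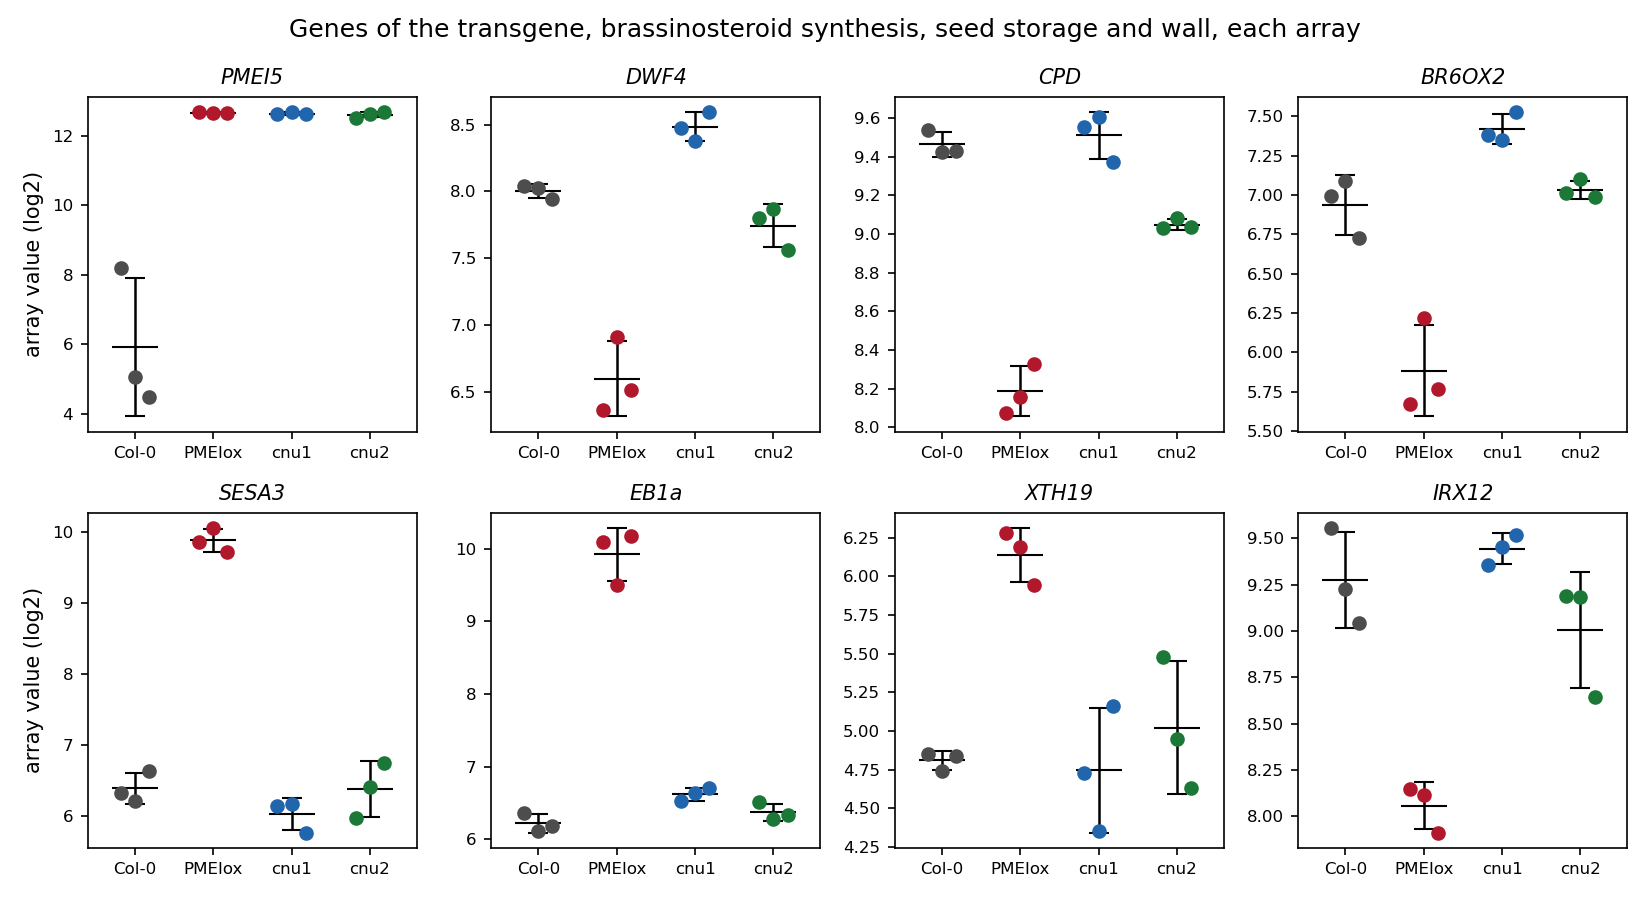
Value of 8 genes on each array, on the log2 scale of the table, with each panel on its own axis that does not start at 0. Points are arrays A, B and C of a genotype from left to right, the bar is the mean with its SD (n = 3), and EB1a averaged 9.92 in PMEIox against 6.22 in Col-0, 6.62 in cnu1 and 6.38 in cnu2.

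The comparison of cnu1 with PMEIox asked what the first suppressor mutation changes in the transgenic background. Seed storage transcripts were lower in cnu1 than in PMEIox, with a list median of -2.20 on the log2 scale, and transcripts of brassinosteroid synthesis (median 0.88) and secondary wall enzymes (median 0.85) were higher. PMEI5 differed by -0.02 ± 0.67 (SE, adjusted p = 0.994), at 12.64 ± 0.04 in cnu1 and 12.66 ± 0.03 in PMEIox (SD, n = 3 each). The SE pools all genotypes and is widened by the spread of PMEI5 within Col-0, which is not part of this comparison. BRI1 differed by 0.34 ± 0.09 (SE, adjusted p = 0.0524) and RLP44 by 0.33 ± 0.20 (SE, adjusted p = 0.397).

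In cnu1, 1792 loci passed the test against PMEIox, 986 higher and 806 lower, of which 218 and 171 differed at least 2-fold. AT2G16005 rose by 3.31 ± 0.26 (SE, adjusted p = 1.17e-05) and CYP705A5 by 3.23 ± 0.24 (SE, adjusted p = 8.00e-06). AT5G57785, AT4G11320, AT1G55240, AT4G17470, BGLU28 (AT2G44460), a glucosidase gene that responds to sulfur supply, LAC2, AT4G11190 and AT3G53250 also rose, from 2.45 for AT3G53250 to 3.13 for AT5G57785. EARLI1 fell by 4.60 ± 0.37 (SE, adjusted p = 1.57e-05). EB1a fell to 6.62 ± 0.09 (SD, n = 3). SESA3, AT5G42530, LCR67, SESA5 (AT5G54740), SESA1, AT5G39150, CLE6 (AT2G31085), which encodes a signalling peptide, and CRU3 fell, with log2 differences from -3.86 for SESA3 to -2.77 for CRU3. AT5G39150 in cnu1 (1.87) and AT3G53250 in PMEIox (2.75) were near background, so their differences are lower bounds. The 3 values of each genotype did not overlap at 25.9% of all loci, where chance gives 10%. The replicate block gave 1871 loci, a minimum fold of 2 389, and leaving out cnu1 C, PMEIox A or PMEIox C gave 1061, 1104 and 1130.

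The largest list medians between cnu1 and PMEIox were those of seed storage, brassinosteroid synthesis and secondary wall genes. Of 10 brassinosteroid synthesis genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.88, camera adjusted p = 6.24e-08, and adjusted p = 0.0258 with an estimated correlation). DWF4 rose by 1.89 ± 0.14 (SE, adjusted p = 7.99e-06), from 6.59 ± 0.28 to 8.48 ± 0.11 (SD, n = 3 each). CPD rose by 1.32, BR6OX2 by 1.54 and CYP90D1 by 1.15. Of 10 secondary wall and lignin genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.85, camera adjusted p = 2.07e-09, and adjusted p = 0.0258 with an estimated correlation), with IRX12 at 1.38. Of 13 seed storage markers, 0 rose and 12 fell (0 and 13 adjusted over the list alone, median -2.20, camera adjusted p = 1.86e-23, and adjusted p = 0.0157 with an estimated correlation). Among them were SESA3 at -3.86 and OLEO1 at -2.07. The storage gene CRA1, named here after its values were seen, varied between replicates. It read 8.77, 6.77 and 9.78 in cnu1 A, B and C, against 6.62 to 6.99 in Col-0.

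Hormone lists with smaller medians were also called between cnu1 and PMEIox. Of 7 brassinosteroid catabolism genes, 1 rose and 2 fell (1 and 5 adjusted over the list alone, median -0.48, camera adjusted p = 0.0161, and adjusted p = 0.254 with an estimated correlation), with BAS1 at -0.94. Of 16 brassinosteroid signalling genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.0366, and adjusted p = 0.345 with an estimated correlation). BRL1 (AT1G55610) was the called gene, a homologue of BRI1, at 0.64, whose call ended without cnu1 A, cnu1 B, cnu1 C, PMEIox B or PMEIox C (adjusted p from 0.0568 to 0.134). The signalling list call ended without cnu1 B (adjusted p = 0.0776), cnu1 C (adjusted p = 0.183), PMEIox B (adjusted p = 0.0728) or PMEIox C (adjusted p = 0.058) and without the lowest 40% of loci (adjusted p = 0.165). Of 16 ethylene genes, 0 rose and 3 fell (0 and 6 adjusted over the list alone, median -0.09, camera adjusted p = 0.0232, and adjusted p = 0.254 with an estimated correlation), with ACS8 at -1.03. The ethylene call ended without cnu1 A (adjusted p = 0.0508). Of 17 jasmonate genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0193, and adjusted p = 0.254 with an estimated correlation), with JR1 at 1.97. The jasmonate call ended without the lowest 40% of loci (adjusted p = 0.0752). The calls of the members AOS, JAZ10 and VSP2 ended in 5, 6 and 6 of the omissions of an array (adjusted p up to 0.108, 0.130 and 0.110).

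Wall and stress lists were called between cnu1 and PMEIox as well. Of 31 pectin methylesterases, 2 rose and 6 fell (4 and 9 adjusted over the list alone, median -0.14, camera adjusted p = 0.0161, and adjusted p = 0.254 with an estimated correlation). One of them was AT5G04970 at -1.87. The pectin methylesterases call ended without cnu1 B (adjusted p = 0.0538). Of 33 XTH genes, 0 rose and 7 fell (3 and 9 adjusted over the list alone, median -0.23, camera adjusted p = 0.0161, and adjusted p = 0.258 with an estimated correlation), with XTH19 (AT4G30290) at -1.39. The XTH call ended without cnu1 B (adjusted p = 0.0776). Of 18 pectin depolymerases, 0 rose and 3 fell (2 and 8 adjusted over the list alone, median -0.27, camera adjusted p = 0.0277, and adjusted p = 0.254 with an estimated correlation). One of them was AT5G63180 at -1.09. The pectin depolymerases call ended without cnu1 B (adjusted p = 0.0791) or PMEIox A (adjusted p = 0.0965). Of 9 pectin synthesis genes, 0 rose and 1 fell (0 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0277, and adjusted p = 0.324 with an estimated correlation). TSD2 (AT1G78240) was the called gene at -0.54. The pectin synthesis call ended without cnu1 A (adjusted p = 0.0508), cnu1 B (adjusted p = 0.0776) or PMEIox A (adjusted p = 0.116). Of 7 heat shock genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone, median -0.46, camera adjusted p = 0.0232, and adjusted p = 0.195 with an estimated correlation), with HSP17.4 at -0.73. The photosynthesis and light list was called lower in cnu1 although its 1 called gene of 22, ELIP2, was higher at 0.73 (0 and 0 adjusted over the list alone, median -0.21, camera adjusted p = 0.0211, and adjusted p = 0.565 with an estimated correlation). The list call ended without cnu1 C (adjusted p = 0.506) or PMEIox C (adjusted p = 0.11) and by fry (adjusted p = 0.283), and that of ELIP2 without cnu1 A, cnu1 B, PMEIox A, PMEIox B or PMEIox C (adjusted p from 0.0529 to 0.161), with the replicate block (adjusted p = 0.0587) and with centring on the reference genes (adjusted p = 0.0558).

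The comparison of cnu2 with PMEIox asked the same of the second suppressor. Seed storage transcripts were lower in cnu2 than in PMEIox, with a list median of -1.83 on the log2 scale, and 10 of 13 markers fell. Brassinosteroid synthesis (median 0.53) and secondary wall lists (median 0.51) were called higher with 5 and 3 of 10 members past limma's test, and both calls ended with an estimated correlation (adjusted p = 0.0749 each). PMEI5 differed by -0.05 ± 0.67 (SE, adjusted p = 0.982), at 12.61 ± 0.08 (SD, n = 3) in cnu2. Here too the spread of PMEI5 within Col-0 widens the SE. BRI1 differed by 0.32 ± 0.09 (SE, adjusted p = 0.0935) and RLP44 by -0.01 ± 0.20 (SE, adjusted p = 0.988).

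In cnu2, 905 loci passed the test against PMEIox, 494 higher and 411 lower, of which 81 and 115 differed at least 2-fold. ENODL1 rose by 2.83 ± 0.21 (SE, adjusted p = 3.18e-05) and AT5G57785 by 2.07 ± 0.19 (SE, adjusted p = 0.000128). AT4G38080, CYP710A2, LAC2, AT2G22510, CYP705A5, AT4G11320 and AT4G17470 also rose, from 1.71 for AT4G17470 to 2.03 for AT4G38080. PELPK1 (AT5G09530) rose by 1.73. The PELPK1 call ended without cnu2 A, cnu2 B, PMEIox A or PMEIox C (adjusted p from 0.0793 to 0.141). EB1a fell by 3.55 ± 0.16 (SE, adjusted p = 7.99e-07) and SESA3 by 3.51 ± 0.19 (SE, adjusted p = 5.04e-06). SESA1, EARLI1, the storage protein gene PAP85 (AT3G22640), CRU3, SESA5, AT1G54870 and AT5G39150 fell, with log2 differences from -3.37 for SESA1 to -2.36 for AT5G39150. LCR67 fell by 2.84. The LCR67 call ended without cnu2 B (adjusted p = 0.0568) or PMEIox C (adjusted p = 0.058). With AT2G22510 at 2.57 in PMEIox and AT5G39150 at 2.72 in cnu2, both near background, these differences are lower bounds. The 3 values of each genotype did not overlap at 22.6% of all loci, where chance gives 10%. The replicate block gave 975 loci, the fit of these genotypes alone 441, eBayes with trend and robust settings 1490 and a minimum fold of 2 196. Leaving out cnu2 A, B or C gave 507, 395 and 602 loci, and leaving out PMEIox A, B or C 428, 581 and 465.

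Seed storage, brassinosteroid synthesis and secondary wall lists were called between cnu2 and PMEIox. Of 13 seed storage markers, 0 rose and 10 fell (0 and 13 adjusted over the list alone, median -1.83, camera adjusted p = 1.90e-24, and adjusted p = 0.0137 with an estimated correlation). Among them were SESA3 at -3.51 and OLEO1 at -1.73. Of 10 brassinosteroid synthesis genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 1.28e-05, and adjusted p = 0.0749 with an estimated correlation). Among them were BR6OX2 at 1.15 and CPD at 0.86. DWF4 rose by 1.15 ± 0.14 (SE, adjusted p = 0.00077) and stood at 7.74 ± 0.16 (SD, n = 3) in cnu2. Of 10 secondary wall and lignin genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 1.25e-06, and adjusted p = 0.0749 with an estimated correlation), with IRX12 at 0.95. The calls of CESA4 (adjusted p from 0.0615 to 0.171) and XCP1 (adjusted p from 0.0528 to 0.0882) ended in 6 and 4 of the omissions of an array.

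Root hair, wall and light lists were lower in cnu2 than in PMEIox. Of 15 root hair markers, 0 rose and 2 fell (0 and 9 adjusted over the list alone, median -0.79, camera adjusted p = 1.03e-05, and adjusted p = 0.147 with an estimated correlation). EXT10 fell by 2.03. The EXT10 call ended without cnu2 A, cnu2 B or PMEIox A (adjusted p from 0.0528 to 0.089). PRP3 (AT3G62680) fell by at least 1.09, to 2.39, near background. The PRP3 call ended without cnu2 A, cnu2 B, cnu2 C or PMEIox A (adjusted p from 0.0511 to 0.075). Of 18 pectin depolymerases, 0 rose and 4 fell (1 and 8 adjusted over the list alone, median -0.25, camera adjusted p = 0.000269, and adjusted p = 0.12 with an estimated correlation). One of them was AT1G67750 at -0.68. The calls of AT3G27400, AT3G24670 and PGAZAT ended in 6, 5 and 4 of the omissions of an array. Their adjusted p then ran from 0.0589 to 0.106, from 0.0745 to 0.172 and from 0.0506 to 0.0831. Of 33 XTH genes, 0 rose and 6 fell (0 and 9 adjusted over the list alone, median -0.24, camera adjusted p = 0.000269, and adjusted p = 0.17 with an estimated correlation). Among them were XTH33 at -0.88 and XTH9 (AT4G03210) at -1.12. Of 31 pectin methylesterases, 0 rose and 2 fell (2 and 7 adjusted over the list alone, median -0.13, camera adjusted p = 0.00465, and adjusted p = 0.178 with an estimated correlation), namely AT5G04970 at -1.19 and AT2G26440 at -1.09. Of 9 pectin synthesis genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 0.0129, and adjusted p = 0.302 with an estimated correlation). The pectin synthesis call ended without cnu2 C (adjusted p = 0.142) or PMEIox A (adjusted p = 0.0699) and by fry (adjusted p = 0.0506). Of 7 heat shock genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 0.0129, and adjusted p = 0.122 with an estimated correlation). HSP17.4 was the called gene at -0.78. Of 22 photosynthesis and light markers 0 passed limma's test, with 4 at an unadjusted p under 0.05. Camera called the list lower (0 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 0.000568, and adjusted p = 0.395 with an estimated correlation). The photosynthesis and light call ended by fry (adjusted p = 0.158).

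**Figure D2:**
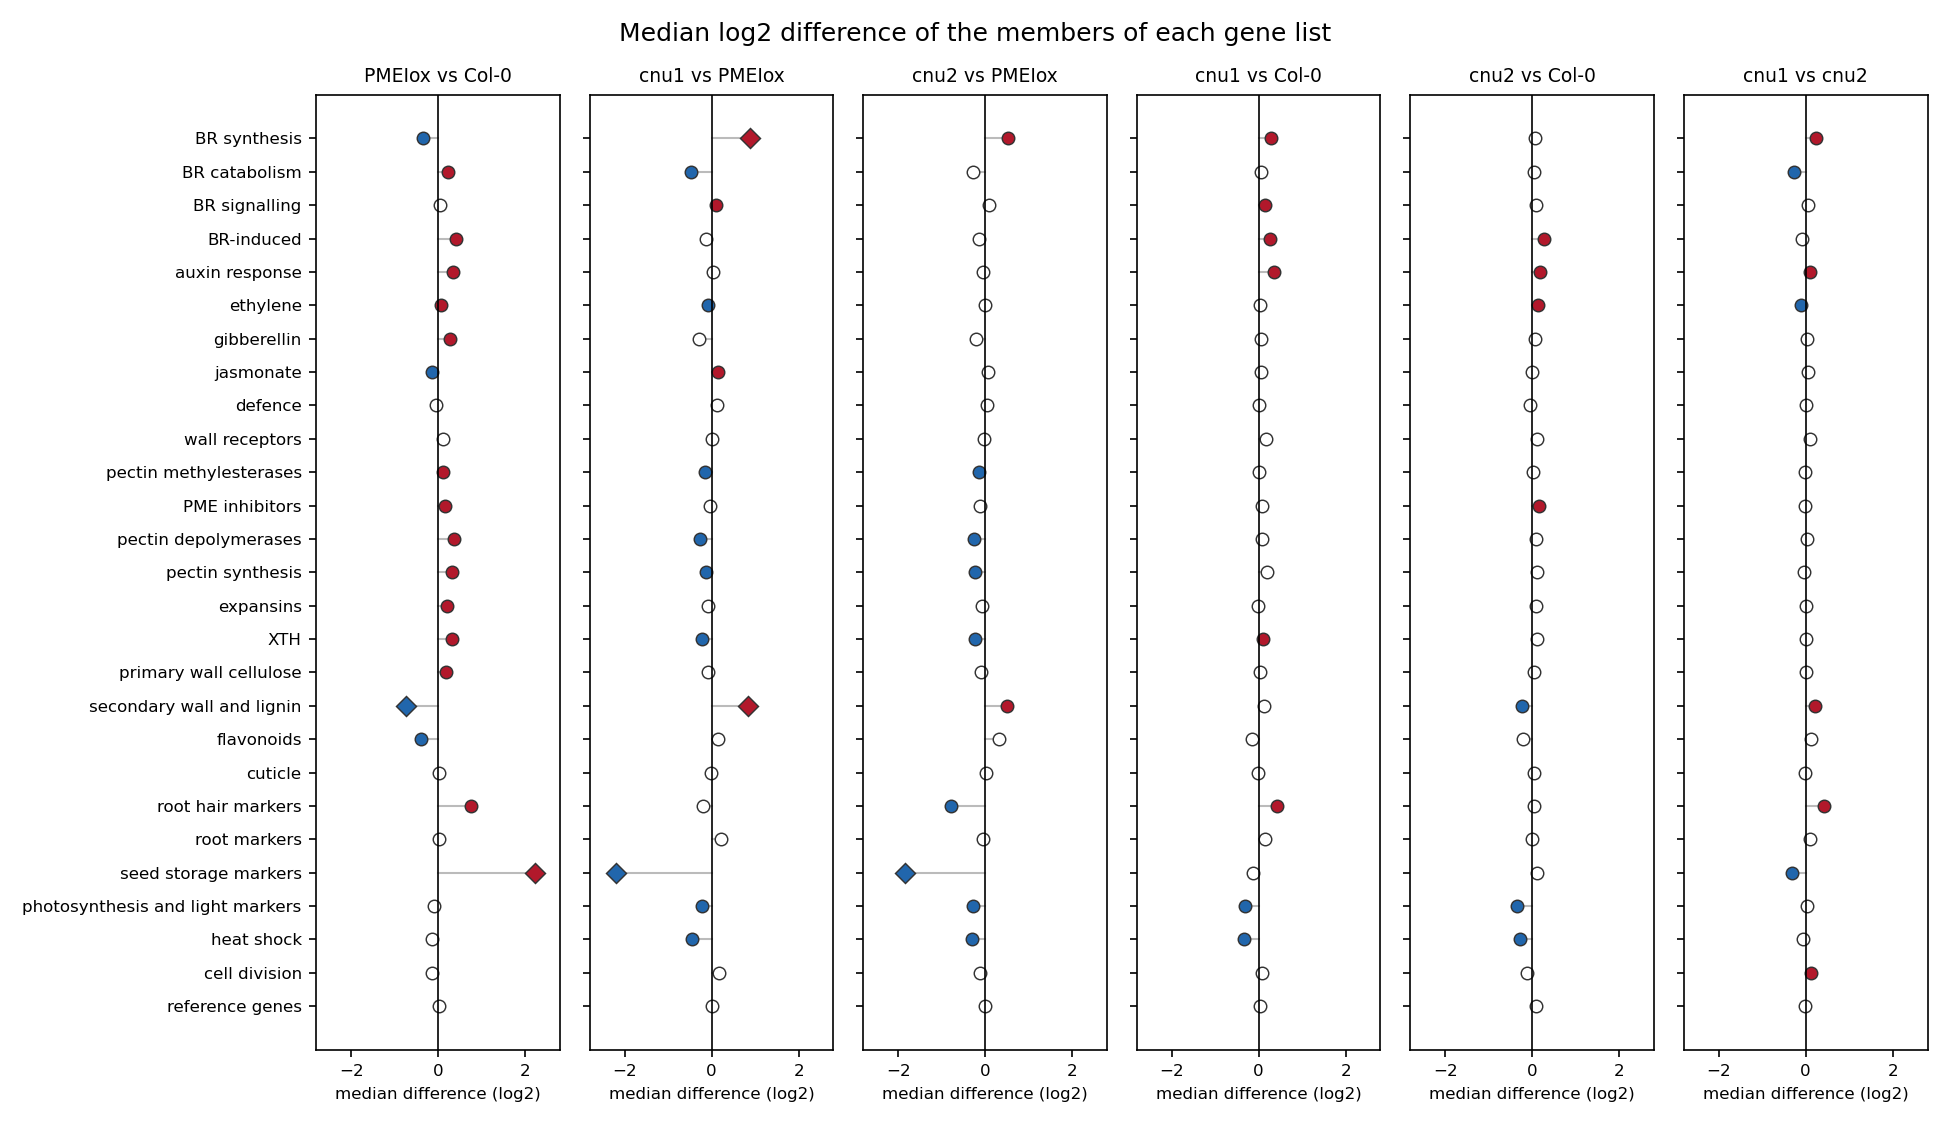
Median log2 difference of the members of each of 27 gene lists in the 6 comparisons, where filled symbols are lists called by camera with the preset correlation (red above 0 and blue below), diamonds those also called with an estimated correlation, and open circles lists that were not called. The list of inhibitors includes the transgene PMEI5. The seed storage median was 2.22 in PMEIox against Col-0, -2.20 in cnu1 against PMEIox and -1.83 in cnu2 against PMEIox.

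The genes that differed between PMEIox and Col-0 were then followed into the suppressors. Of these 1460 loci, 885 (60.6%) were called in the opposite direction in cnu1 against PMEIox and 592 (40.5%) in cnu2 against PMEIox, and 515 were in both groups. EB1a, SESA3, EARLI1, CYP705A5, DWF4, AT5G04970 and JR1 were among the 515. By limma's test 0 loci moved further from Col-0, which the sharing of the PMEIox arrays also makes less likely. Against Col-0, 52 of the 1460 loci were called in cnu1, 38 of them in the direction of PMEIox, and 40 in cnu2, all in that direction. Across all genes, which are not independent replicates, the PMEIox difference had a Pearson correlation of -0.701 with the cnu1 difference and -0.713 with the cnu2 difference. In 100 simulated sets of unchanged groups sharing the PMEIox arrays the means were -0.501 and -0.501, and the covariance was -0.0673 for cnu1 and -0.0586 for cnu2 against -0.0123 in both simulations. The count for cnu1 was 953 with the replicate block, 212 with a minimum fold of 2 and 572 without PMEIox A. For cnu2 it was 649 with the block, 929 with trend and robust eBayes, 148 with a minimum fold of 2, 380 without cnu2 A, 326 without cnu2 B, 337 without PMEIox A and 362 without PMEIox C.

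A score placed each array between Col-0 (0) and PMEIox (100) over the 1459 changed loci other than PMEI5. The cnu1 arrays scored 13.1 ± 3.36 (SD, n = 3), from 9.58 to 16.3, and the cnu2 arrays 30.7 ± 1.86 (SD, n = 3), from 28.7 to 32.4. The suppressors did not overlap, and an exact two-sided permutation test gave p = 0.1, the smallest it can give. The loci were chosen on the Col-0 and PMEIox arrays, which widens the distance between these genotypes. The PMEIox difference and the difference of cnu1 from cnu2 share no arrays, and across all genes, which are not independent replicates, their Pearson correlation was -0.136. The simulated range was -0.0164 to 0.0123, but it leaves out deviations that arrays have in common. Deviations of arrays from their group means correlated across genes from -0.137 to 0.190 between genotypes, so this range cannot serve as a test. Of the loci called in both, 70 had opposite signs and 8 the same sign.

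**Figure D3:**
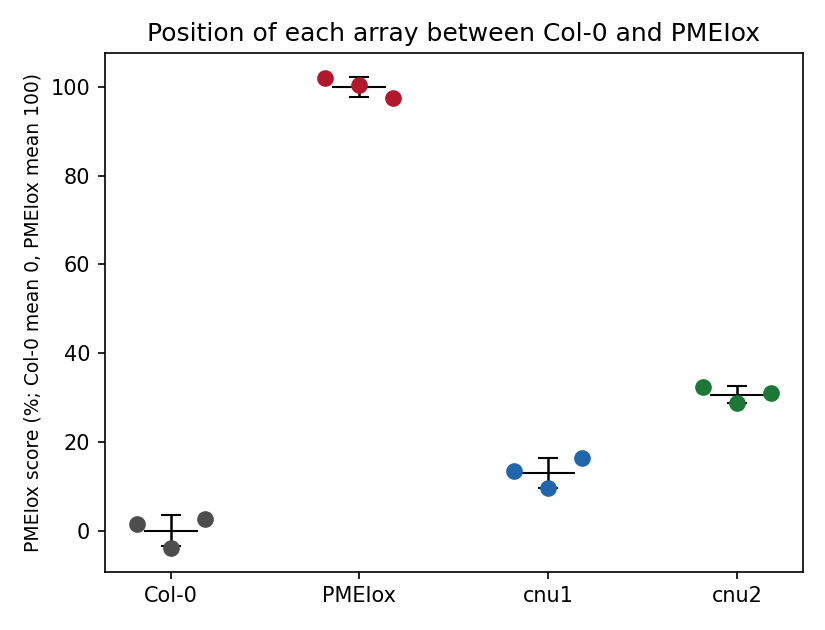
Score of each array over the 1459 loci changed in PMEIox other than PMEI5, in percent, with the Col-0 mean at 0 and the PMEIox mean at 100. Points are arrays A, B and C from left to right, bars the mean and SD (n = 3), and the cnu1 arrays lie from 9.58 to 16.3 and the cnu2 arrays from 28.7 to 32.4.

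The comparison of cnu1 with Col-0 asked what remains different in the first suppressor line, which carries the transgene and the suppressor mutation. PMEI5 was higher by 6.73 ± 0.67 (SE, adjusted p = 0.00109), and by 7.87 without Col-0 A. ATSDI1 (AT5G48850), a gene induced by sulfur shortage, rose by 2.54 ± 0.26 (SE, adjusted p = 0.00152), from 3.64 to 6.18, and NUDT8 (AT5G47240) by 2.15 ± 0.15 (SE, adjusted p = 0.000172). AT1G80130 fell by 1.39 ± 0.13 (SE, adjusted p = 0.000993) and AT4G18280 by 1.24 ± 0.15 (SE, adjusted p = 0.0037). BRI1 differed by 0.21 ± 0.09 (SE, adjusted p = 0.357) and RLP44 by 0.25 ± 0.20 (SE, adjusted p = 0.616).

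In cnu1, 173 loci passed the test against Col-0, 100 higher and 73 lower, of which 35 and 21 differed at least 2-fold. AT3G16660 rose by 2.78, UMAMIT35 (AT1G60050) by 2.55, AT3G54580, an extensin-like gene, by 2.48 and SAG29 (AT5G13170), a sugar transporter gene, by 1.74. AT2G31540 at 2.41 or more, RHS19 and AT4G10860 at 1.73 also passed, and of these calls the following numbers ended: 2 without Col-0 A (adjusted p up to 0.133), 2 without Col-0 B (adjusted p up to 0.0677), 1 without Col-0 C (adjusted p = 0.119), 2 without cnu1 A (adjusted p up to 0.101), 1 without cnu1 B (adjusted p = 0.111), 3 without cnu1 C (adjusted p up to 0.201) and 1 with centring on the reference genes (adjusted p = 0.0525). The cold and drought genes KIN2 (AT5G15970), LTI78 (AT5G52310) and RD20 (AT2G33380) fell by 2.14, 1.74 and 1.55, and AT5G54165, AT1G20070, AT5G16980, AT4G28140 and ESM1 (AT3G14210) fell as well, from -1.89 for AT5G54165 to -1.24 for ESM1. Of these 8 calls the following numbers ended: 8 without Col-0 A (adjusted p up to 0.151), 8 without Col-0 B (adjusted p up to 0.126), 6 without cnu1 A (adjusted p up to 0.112), 5 without cnu1 B (adjusted p up to 0.0903), 7 without cnu1 C (adjusted p up to 0.211) and 1 with the replicate block (adjusted p = 0.0604). In Col-0 AT2G31540 stood at 2.19, near background, so its difference is at least that given. The 3 values of each genotype did not overlap at 19.6% of all loci, where chance gives 10%. The replicate block gave 179 loci, the fit of these genotypes alone 55, trend and robust eBayes 631, the table without its lowest 40% of loci 439 and a minimum fold of 2 56. Leaving out cnu1 A, B or C gave 89, 85 and 45 loci, and leaving out Col-0 A or B 53 and 76. With centring on the reference genes 82 loci were higher and 87 lower, which gives 48.5% higher in place of 57.8%.

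Hormone lists called between cnu1 and Col-0 held few called genes. Of 10 brassinosteroid synthesis genes, 1 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 5.74e-05, and adjusted p = 0.251 with an estimated correlation). BR6OX1 (AT5G38970) was the called gene at 0.86, whose call ended without cnu1 B, cnu1 C, Col-0 A or Col-0 B (adjusted p from 0.0555 to 0.109). Of 33 auxin response genes 0 passed limma's test, with 17 at an unadjusted p under 0.05. Camera called the list higher (9 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 3.06e-09, and adjusted p = 0.251 with an estimated correlation). The auxin response call ended by fry (adjusted p = 0.0505). Of 16 brassinosteroid signalling genes 0 passed, with 3 at an unadjusted p under 0.05 in limma. Camera called the list higher (0 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 0.0165, and adjusted p = 0.458 with an estimated correlation). The signalling call ended without cnu1 C (adjusted p = 0.201), by fry (adjusted p = 0.121) and without the lowest 40% of loci (adjusted p = 0.0508). Of 16 brassinosteroid-induced genes 0 passed, with 7 at an unadjusted p under 0.05 in limma. Camera called the list higher (2 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 0.0165, and adjusted p = 0.46 with an estimated correlation). The brassinosteroid-induced call ended without cnu1 C (adjusted p = 0.201) or Col-0 A (adjusted p = 0.0542) and by fry (adjusted p = 0.171).

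Wall, root hair, light and heat shock lists were also called between cnu1 and Col-0. Of 33 XTH genes, 1 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 0.0384, and adjusted p = 0.46 with an estimated correlation). The XTH call ended without cnu1 A (adjusted p = 0.0841), cnu1 C (adjusted p = 0.201), Col-0 A (adjusted p = 0.128) or Col-0 B (adjusted p = 0.0508), by fry (adjusted p = 0.171) and without the lowest 40% of loci (adjusted p = 0.075). The called gene, XTH16 (AT3G23730), rose by 0.79, and its call ended without Col-0 A (adjusted p = 0.067) or Col-0 B (adjusted p = 0.0598). Of 15 root hair markers, 1 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 3.60e-06, and adjusted p = 0.251 with an estimated correlation). The root hair list call ended by fry (adjusted p = 0.0505). The called gene, RHS19, lost its call without cnu1 A, cnu1 B, cnu1 C, Col-0 A, Col-0 B or Col-0 C (adjusted p from 0.0677 to 0.201) and with centring on the reference genes (adjusted p = 0.0525). Of 22 photosynthesis and light markers 0 passed limma's test, with 7 at an unadjusted p under 0.05. Camera called the list lower (0 and 0 adjusted over the list alone, median -0.31, camera adjusted p = 8.08e-07, and adjusted p = 0.458 with an estimated correlation). The photosynthesis and light call ended by fry (adjusted p = 0.139). Of 7 heat shock genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone, median -0.33, camera adjusted p = 0.0384, and adjusted p = 0.251 with an estimated correlation). The heat shock call ended without cnu1 A (adjusted p = 0.0718), cnu1 C (adjusted p = 0.0803), Col-0 A (adjusted p = 0.0609) or Col-0 B (adjusted p = 0.137), with the replicate block (adjusted p = 0.0544) and with centring on the reference genes (adjusted p = 0.0581). HSP70 (AT3G12580) at -0.66 lost its call without cnu1 A, cnu1 B, cnu1 C, Col-0 A or Col-0 B (adjusted p from 0.0503 to 0.13) and with the replicate block (adjusted p = 0.0508), and HSP101 (AT1G74310) at -0.77 lost its call without cnu1 B, cnu1 C, Col-0 A, Col-0 B or Col-0 C (adjusted p from 0.0695 to 0.168) and with the replicate block (adjusted p = 0.0571).

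The comparison of cnu2 with Col-0 asked the same of the second suppressor line. PMEI5 was higher by 6.70 ± 0.67 (SE, adjusted p = 0.00498), and by 7.84 without Col-0 A. ACS8, an ethylene synthesis gene, rose by 1.25 ± 0.13 (SE, adjusted p = 0.00498), from 5.69 to 6.94. AZI1 (AT4G12470), a lipid transfer protein gene, rose by 1.37 ± 0.16 (SE, adjusted p = 0.00584). AT2G17080 fell by 1.81 ± 0.20 (SE, adjusted p = 0.00584) and AT4G11320 by 1.16 ± 0.13 (SE, adjusted p = 0.00584). BRI1 differed by 0.19 ± 0.09 (SE, adjusted p = 0.488) and RLP44 by -0.09 ± 0.20 (SE, adjusted p = 0.915).

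In cnu2, 52 loci passed the test against Col-0, 30 higher and 22 lower, of which 5 and 7 differed at least 2-fold. AT3G29644 rose by 0.91, AT2G37030 fell by 1.08 and GH9B8 (AT2G32990), an endoglucanase gene, fell by 0.94. AT2G16005 fell by 2.15. The AT2G16005 call ended without Col-0 B (adjusted p = 0.0528). AT3G16660 at 1.65, AT3G14380, UMAMIT34 (AT4G30420), the auxin synthesis gene YUC3 (AT1G04610), AT5G67020 and AT1G23510 at 0.88 also rose, and AT4G11210 at -1.51, CYP705A5 at -1.40, AT4G37409, AT4G11190 and UGT75B1 (AT1G05560) at -0.94 fell. Of these last 11 calls the following numbers ended: 8 without Col-0 A (adjusted p up to 0.134), 10 without Col-0 B (adjusted p up to 0.138), 10 without Col-0 C (adjusted p up to 0.0993), 10 without cnu2 A (adjusted p up to 0.163), 7 without cnu2 B (adjusted p up to 0.18), 10 without cnu2 C (adjusted p up to 0.121) and 6 with the replicate block (adjusted p up to 0.0707). The 3 values of each genotype did not overlap at 15.5% of all loci, where chance gives 10%. The fit of these genotypes alone called 0 loci, with 2798 at an unadjusted p under 0.05 in limma, trend and robust eBayes called 236, the table without its lowest 40% of loci 117, a minimum fold of 2 12 and the replicate block 41. Leaving out cnu2 A, B or C gave 11, 16 and 11 loci, and leaving out Col-0 A, B or C 14, 10 and 27. With centring on the reference genes 18 loci were higher and 23 lower, so 43.9% were higher in place of 57.7%.

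Hormone lists were called higher in cnu2 than in Col-0. Of 16 ethylene genes, 1 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.000316, and adjusted p = 0.276 with an estimated correlation). ACS8 was the called gene. Of 16 brassinosteroid-induced genes, 1 rose and 0 fell (6 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.000636, and adjusted p = 0.336 with an estimated correlation). The brassinosteroid-induced call ended by fry (adjusted p = 0.122). The called gene, KDR (AT1G26945), rose by 0.46, and its call ended without cnu2 A, cnu2 B, cnu2 C, Col-0 A, Col-0 B or Col-0 C (adjusted p from 0.0882 to 0.17), with the replicate block (adjusted p = 0.0608) and with centring on the reference genes (adjusted p = 0.109). Of 33 auxin response genes 0 passed limma's test, with 8 at an unadjusted p under 0.05. Camera called the list (7 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 2.01e-05, and adjusted p = 0.336 with an estimated correlation). The auxin response call ended by fry (adjusted p = 0.143). Of 13 pectin methylesterase inhibitors 1 rose, the transgene PMEI5 itself, and camera did not call the other 12 (adjusted p = 0.221), with PMEI5 left out after seeing the data.

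Light, secondary wall and heat shock lists were called lower in cnu2 than in Col-0. Of 22 photosynthesis and light markers 0 passed limma's test, with 12 at an unadjusted p under 0.05 (0 and 8 adjusted over the list alone, median -0.35, camera adjusted p = 2.10e-09, and adjusted p = 0.336 with an estimated correlation). The photosynthesis and light call ended by fry (adjusted p = 0.122). Of 10 secondary wall genes 0 passed limma's test, with 1 at an unadjusted p under 0.05 (0 and 1 adjusted over the list alone, median -0.22, camera adjusted p = 0.0133, and adjusted p = 0.336 with an estimated correlation). The secondary wall call ended without cnu2 C (adjusted p = 0.152) and by fry (adjusted p = 0.136). Of 7 heat shock genes 0 passed limma's test, with 3 at an unadjusted p under 0.05 (0 and 2 adjusted over the list alone, median -0.27, camera adjusted p = 0.0175, and adjusted p = 0.276 with an estimated correlation). The heat shock call ended without Col-0 B (adjusted p = 0.106).

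Loci called against Col-0 in both suppressor lines numbered 12, 7 higher and 5 lower. Of these, 8 were also called in PMEIox against Col-0 in the same direction, and both lines carry that transgene. With PMEI5, the transcription factor genes WRKY70 (AT3G56400) (0.66 in cnu1 and 0.67 in cnu2) and MYB45 (AT3G48920), AT3G16660, AT3G29644, AT1G44830 and AT5G15180 were higher in both lines. AOR (AT1G23740), UGT76E11 (AT3G46670), CHX10 (AT3G44930), FKBP13 (AT5G45680) and CYP83B1 (AT4G31500), a gene of indole glucosinolate synthesis (-0.57 and -0.75), were lower in both. Both comparisons share the Col-0 arrays, and across all genes, which are not independent replicates, their differences had a Pearson correlation of 0.586, where 100 simulated sets of unchanged groups sharing these arrays gave 0.481 to 0.514. The simulated sets leave out deviations that arrays have in common, so that range is too narrow for a test. The number called in both was 5 without cnu1 A, 5 without cnu1 B, 3 without cnu1 C, 3 without each of cnu2 A, cnu2 B and cnu2 C, 4 without Col-0 A, 2 without Col-0 B and 9 without Col-0 C. It was 5, 6 and 6 without PMEIox A, B and C, which enter only through the variance, and 8 with the replicate block. Apart from those among the largest changes, these genes were named after their values were seen.

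The comparison of cnu1 with cnu2 asked where the suppressors differ, and it is also the test of the difference between their effects on PMEIox. BGLU28 was higher in cnu1 by 2.59 ± 0.19 (SE, adjusted p = 0.000236), at 6.60 against 4.01, and ATSDI1 by 2.23 ± 0.26 (SE, adjusted p = 0.00338). ACS8, an ethylene synthesis gene, was lower in cnu1 than in cnu2, with a difference of -0.87 ± 0.13 (SE, adjusted p = 0.00937). PMEI5 differed by 0.03 ± 0.67 (SE, adjusted p = 0.998), BRI1 by 0.02 ± 0.09 (SE, adjusted p = 0.99) and RLP44 by 0.34 ± 0.20 (SE, adjusted p = 0.72). The SE of PMEI5 pools all genotypes and is widened by its spread within Col-0. On the cnu1, cnu2 and PMEIox arrays PMEI5 lay from 12.53 to 12.69.

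Between the suppressors 158 loci passed the test, 105 higher in cnu1 and 53 lower, of which 39 and 20 differed at least 2-fold. AT2G16005, AT2G31540, AT2G17080, AT3G54580, UMAMIT35, NUDT8 and CYP708A2 (AT5G48000), a thalianol metabolism gene, were higher in cnu1, from 1.42 for CYP708A2 to 3.01 for AT2G16005. AT5G42530, AT3G29970, GA2OX8 (AT4G21200), which inactivates gibberellin, ADH1 (AT1G77120), AT2G23540 and LATE (AT5G48890) were lower in cnu1, with differences from -1.65 for AT5G42530 to -1.45 for LATE. AT4G38080 at -1.999, AT2G22510 at -1.78, AT4G33070 at -1.49, AT3G60650 at -1.46 and CYP705A5 at 1.41 were called as well, and of these 5 calls the following numbers ended: 5 without cnu1 A (adjusted p up to 0.123), 3 without cnu1 B (adjusted p up to 0.0868), 3 without cnu1 C (adjusted p up to 0.0957), 2 without cnu2 A (adjusted p up to 0.079) and 2 without cnu2 B (adjusted p up to 0.0803). Near background were AT2G31540 in cnu2 (2.27) and AT2G22510 in cnu1 (2.63), so their differences are lower bounds. The 3 values of each genotype did not overlap at 13.2% of all loci, where chance gives 10%. The replicate block gave 172 loci, the fit of these genotypes alone 89, trend and robust eBayes 267 and a minimum fold of 2 59. Leaving out cnu1 A, B or C gave 66, 74 and 76 loci, and leaving out cnu2 A, B or C 84, 77 and 79.

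Hormone lists were called between the suppressors, where rose and fell stand for higher and lower in cnu1. Of 10 brassinosteroid synthesis genes, 2 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 1.95e-05, and adjusted p = 0.156 with an estimated correlation). DWF4 was higher in cnu1 by 0.74. The DWF4 call ended without cnu1 A, cnu1 B, cnu1 C, cnu2 A, cnu2 B or cnu2 C (adjusted p from 0.0726 to 0.144) and with the replicate block (adjusted p = 0.0509). BR6OX1 was higher by 0.84. The BR6OX1 call ended without cnu1 B, cnu1 C, cnu2 A, cnu2 B or cnu2 C (adjusted p from 0.0624 to 0.103). Of 16 ethylene genes, 0 rose and 1 fell (0 and 4 adjusted over the list alone, median -0.10, camera adjusted p = 0.000144, and adjusted p = 0.156 with an estimated correlation). ACS8 was the called gene. Of 7 brassinosteroid catabolism genes 0 passed limma's test, with 2 at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 0.0329, and adjusted p = 0.349 with an estimated correlation). The catabolism call ended without cnu1 A (adjusted p = 0.0839), cnu1 B (adjusted p = 0.123), cnu2 A (adjusted p = 0.0605) or cnu2 B (adjusted p = 0.0969) and by fry (adjusted p = 0.139). Of 33 auxin response genes, 1 rose and 0 fell (1 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 0.0387, and adjusted p = 0.802 with an estimated correlation). The auxin response call ended without cnu1 C (adjusted p = 0.918), cnu2 A (adjusted p = 0.121) or cnu2 C (adjusted p = 0.159), by fry (adjusted p = 0.622) and without the lowest 40% of loci (adjusted p = 0.19). IAA29 at 0.70 was the called gene, and its call ended without cnu1 A, cnu1 B, cnu1 C, cnu2 A, cnu2 B or cnu2 C (adjusted p from 0.0959 to 0.16).

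Root hair, secondary wall, seed and cell division lists were called between cnu1 and cnu2 without a member past limma's test. Of 15 root hair markers 8 had an unadjusted p under 0.05 (5 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 1.53e-05, and adjusted p = 0.21 with an estimated correlation). The root hair list call ended by fry (adjusted p = 0.113). Of 10 secondary wall genes 4 had an unadjusted p under 0.05 (4 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.00055, and adjusted p = 0.21 with an estimated correlation). The secondary wall call ended by fry (adjusted p = 0.113). Of 13 seed storage markers 4 had an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, median -0.31, camera adjusted p = 0.0048, and adjusted p = 0.443 with an estimated correlation). The seed storage call ended without cnu1 B (adjusted p = 0.105) or cnu2 C (adjusted p = 0.0969) and by fry (adjusted p = 0.421). Of 8 cell division genes 2 had an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.0103, and adjusted p = 0.235 with an estimated correlation). The cell division call ended without cnu1 C (adjusted p = 0.0595) or cnu2 B (adjusted p = 0.0665), by fry (adjusted p = 0.113) and without the lowest 40% of loci (adjusted p = 0.19).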

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

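The tests of storage genes outside the SESA family and of a wrong label for Col-0 A were chosen after the result was seen.

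The effects of cnu1 and cnu2 on the PMEIox line differed at 158 loci by the test of the difference itself. Higher in cnu1 were AT2G16005 (3.01), BGLU28 (2.59), AT2G31540 (2.32), ATSDI1 (2.23), AT2G17080 (2.15), AT3G54580 (2.12), UMAMIT35 (1.81), NUDT8 (1.68), CYP708A2 (1.42), CYP705A5 (1.41), BR6OX1 (0.84), DWF4 (0.74), EDS16 (0.71) and IAA29 (0.70). Lower in cnu1 were AT4G38080 (-1.999), AT2G22510 (-1.78), AT5G42530 (-1.65), AT3G29970 (-1.52), GA2OX8 (-1.50), AT4G33070 (-1.49), ADH1 (-1.46), AT3G60650 (-1.46), AT2G23540 (-1.45), LATE (-1.45), ACS8 (-0.87) and AT5G04970 (-0.68). Of these 26 gene calls the following numbers ended: 9 without cnu1 A (adjusted p up to 0.18), 7 without cnu1 B (adjusted p up to 0.117), 8 without cnu1 C (adjusted p up to 0.166), 7 without cnu2 A (adjusted p up to 0.132), 7 without cnu2 B (adjusted p up to 0.136), 5 without cnu2 C (adjusted p up to 0.149) and 1 with the replicate block (adjusted p = 0.0509). AT2G31540 in cnu2 and AT2G22510 in cnu1 were near background, so their differences are lower bounds. The number of loci was 66 without cnu1 A, 74 without cnu1 B, 76 without cnu1 C, 84 without cnu2 A, 77 without cnu2 B and 79 without cnu2 C.

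Seed storage transcripts were higher in PMEIox than in Col-0. Within each suppressor CRA1 varied widely between replicates, while SESA3 varied less. Probes shared among the tandem SESA genes would limit the rise to these, but the 8 other storage markers had a median of 1.79 and 7 of them rose. Seed tissue at an earlier stage in the PMEIox samples would raise late seed genes outside the list, and the median of 24 such genes was 0.59 (10 rose and 1 fell, camera p = 2.29e-08, and p = 0.0297 with an estimated correlation, or 0.0667 adjusted over 18 tests). Of the 24, 17 were higher and 7 lower, of which ABI5 fell by 0.51 and the others, from -0.48 for BETA-TIP to -0.12 for AT3G02480, did not pass limma's test. A slower passage from seed to seedling, uneven germination in the samples, or an effect of the transgene on seed genes may each account for the rise, and these data hold no measure of stage that separates them.

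PMEI5 stood at 8.19 in Col-0 A against 5.05 in Col-0 B and 4.49 in Col-0 C. A wrong label would place Col-0 A near the transgenic arrays, but the lowest of these was higher by 4.34. PMEIox RNA in Col-0 A would need a share of 4.09%. For 27 genes at least 4-fold higher in PMEIox than in the suppressors, that share predicts a median excess of 0.256. The observed median was 0.0144, with Col-0 B at -0.121 and Col-0 C at 0.154. A 95% bootstrap interval of -0.0918 to 0.0894 resampled these genes, so it does not measure the spread between arrays. Col-0 B and C lay outside it. The predicted excess lay above the values of all 3 Col-0 arrays, but 3 arrays are too few to exclude PMEIox RNA. RNA of a suppressor line in Col-0 A was not tested and stays open, as does a signal particular to the PMEI5 probes. The design gives no biological explanation that was tested.

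Loci changed in PMEIox moved back in both suppressors, and sharing of the PMEIox arrays alone would give covariances in the simulated range, but the covariance was -0.0673 for cnu1 and -0.0586 for cnu2 against means of -0.0123. The simulated sets leave out other deviations that arrays have in common. For a single deviating PMEIox array the prediction was that leaving it out would more than halve the counts. The lowest counts were 572 of 885 for cnu1 and 337 of 592 for cnu2, both without PMEIox A, and 362 for cnu2 without PMEIox C. Leaving out suppressor arrays gave 380 for cnu2 without cnu2 A and 326 without cnu2 B. Every omission loses a sample, and a deviating array also widens the variance, so these counts cannot decide whether a PMEIox array deviates. That the suppressor mutations reverse part of the transgene's effect on transcripts may be taken as a hypothesis, found and tested on the same data. A difference in stage or growth of the PMEIox samples stays open, since the late seed genes had medians of 0.59 in PMEIox against Col-0, -0.74 in cnu1 against PMEIox and -0.50 in cnu2 against PMEIox (p = 0.0667, 0.0420 and 0.0464 with an estimated correlation, adjusted over 18 tests).

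For each comparison 1 of the 10 splits of the 6 arrays, the real one, gave as many loci, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 1460 and 0 for PMEIox against Col-0, 1792 and 0 for cnu1 against PMEIox, 905 and 1 for cnu2 against PMEIox, 173 and 0 for cnu1 against Col-0, 52 and 1 for cnu2 against Col-0, and 158 and 0 for cnu1 against cnu2.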

How the results depend on the processing

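Centring on the reference genes, and the inhibitor list without PMEI5, were chosen after the result was seen. Quantile normalization and median centring moved no value, since the arrays already share a distribution, and so say nothing about stability. In the order PMEIox against Col-0, cnu1 against PMEIox, cnu2 against PMEIox, cnu1 against Col-0, cnu2 against Col-0 and cnu1 against cnu2, a minimum fold of 2 gave 319, 389, 196, 56, 12 and 59 loci, as its construction requires. The replicate letter as a block gave 1596, 1871, 975, 179, 41 and 172, and array weights 1538, 2080, 1086, 197, 67 and 207. The fit of the compared genotypes alone, which has fewer samples, gave 868 for PMEIox against Col-0, 441 for cnu2 against PMEIox, 55 for cnu1 against Col-0, 0 for cnu2 against Col-0 (2798 at an unadjusted p under 0.05 in limma) and 89 for cnu1 against cnu2. Trend and robust eBayes gave 1490 for cnu2 against PMEIox, 631 for cnu1 against Col-0, 236 for cnu2 against Col-0 and 267 for cnu1 against cnu2, and the cause was not tested. Without the lowest 40% of loci, and so with fewer genes tested, cnu1 against Col-0 gave 439 and cnu2 against Col-0 117. Leaving out an array, and so with fewer samples, gave 882 to 1156, 1061 to 1373, 395 to 602, 45 to 175, 10 to 27 and 66 to 84 loci. Loci moved back in cnu1 numbered 212 with a minimum fold of 2, 953 with the block and 572 to 722 with an array left out, and in cnu2 148, 649 and 326 to 497, and 929 with trend and robust eBayes. Of 162 list tests 64 were called, 6 with an estimated correlation, which allows for correlated members, 53 by fry, 64 with the block, 52 without the lowest 40% of loci, 63 without PMEI5 in the inhibitor list and 58 to 67 with an array left out. Without the lowest 40% of loci, lists left with too few members were not tested, so fewer tests were run. Of 754 gene results 295 were called and 206 of these in every setting run for single genes, and 0 changed direction after being called in limma. Array weights, the fit of the compared genotypes alone and a minimum fold of 2 were not run for single genes. A gene among the lowest 40% of loci was not tested in that setting. Deviations from the group means correlated across genes from -0.137 to 0.190 in 18 same-letter pairs and from -0.131 to 0.125 in 36 others. Of these pairs 7 and 3 exceeded 0.1, the 3 all with a cnu1 array. cnu1 C read 0.125, 0.112 and 0.055 with B of cnu2, PMEIox and Col-0, and -0.137, -0.105 and 0.060 with their C. Of 12 arrays, 10 had their highest mean correlation with their own letter, more than chance gives. The letters may mark a batch, left out of the main fit, but the block may be wrong for cnu1. No label ties a letter to the same week in all genotypes. Signal near background limits loci such as RLP44, whose mean lay above 14.8% of the others.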

Other observations

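The test of neighbouring loci without overlapping pairs was chosen after the result was seen, and the sulfur, cold and neighbour tests were set up because of genes noticed in these data.

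CYP705A5, CYP708A2 and THAS1 belong to the thalianol cluster, which makes a root triterpene. CYP705A5 fell by 3.21 and CYP708A2 by 1.60 in PMEIox against Col-0, while THAS1, the thalianol synthase gene, differed by -0.61 ± 0.20 (SE, adjusted p = 0.12). In cnu1 against PMEIox CYP705A5 rose by 3.23, CYP708A2 by 1.99 and THAS1 by 0.87. In cnu2 against PMEIox CYP705A5 rose by 1.81, CYP708A2 differed by 0.57 ± 0.18 (SE, adjusted p = 0.126) and THAS1 by -0.43 ± 0.20 (SE, adjusted p = 0.32). CYP708A2 and THAS1 were chosen here after their values were seen, and the cluster was not tested as a group.

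Sulfur limitation may be a feature of cnu1, a hypothesis drawn from ATSDI1, LSU1 and BGLU28, of which LSU1 was named after its values were seen. In cnu1 against Col-0 all 8 other sulfur limitation markers were higher, with a median of 0.56, and 1 passed limma's test (camera p = 1.33e-10 and 4.80e-10 adjusted over 18 tests, and 0.000300 and 0.00180 with an estimated correlation). The called gene was AT5G26220 at 0.79. In PMEIox against Col-0 the median was -0.33, with 1 of 8 higher (camera p = 0.00351 adjusted over 18 tests, and 0.0470 with an estimated correlation). Against PMEIox all 8 rose in cnu1, with a median of 0.85, and in cnu2 the median was 0.30 (camera p = 0.00265 adjusted over 18 tests, and 0.0464 with an estimated correlation). In cnu2 against Col-0 the median was -0.03, and in cnu1 against cnu2 it was 0.56, with all 8 higher and 2 past limma's test (camera p = 1.43e-12 adjusted over 18 tests, and 0.00169 with an estimated correlation). Sulfur supply was not measured.

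A lower cold or dehydration response in cnu1 may go with KIN2, LTI78 and RD20. Each of these calls ended without Col-0 A and also without Col-0 B. The 11 other markers were all lower in cnu1 than in Col-0, with a median of -0.35, and 0 passed limma's test, with 6 at an unadjusted p under 0.05 (camera p = 4.90e-06 and 1.26e-05 adjusted over 18 tests, and 0.0492 and 0.0985 with an estimated correlation). In cnu2 against Col-0 the median was -0.34 (camera p = 0.00257, and p = 0.165 with an estimated correlation). In cnu1 against cnu2 it was -0.27 (camera p = 0.0113 and 0.0146 adjusted over 18 tests, and 0.235 and 0.320 with an estimated correlation). In PMEIox against Col-0 the median was -0.14, with 5 of 11 higher (camera p = 0.208, and 0.541 with an estimated correlation). KIN1, LTI65 and GolS2 differed there by -1.37, -1.15 and -0.96, and 0 markers were called. In cnu1 against PMEIox the median was -0.32 (camera p = 0.0118 adjusted over 18 tests, and 0.320 with an estimated correlation). A fall particular to cnu1 is therefore not shown. RAB18 is in this list and in that of late seed genes.

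Loci changed in PMEIox lay next to each other more often than random placement gives, which may reflect shared regulation or probes shared by tandem duplicates, and neither was tested. There were 104 neighbouring pairs called with the same sign, against a mean of 38.3 and a highest count of 66 in 10000 random draws. Without overlapping loci there were 91 pairs, against a mean of 33.4 and a highest count of 58.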
